A study of Mus musculus with 22 samples.

How the data were processed

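The series profiled liver RNA from 22 female C57BL/6 mice in 4 groups, with 1 library per mouse: 6 conventional non-pregnant, 5 conventional pregnant, 6 germ-free non-pregnant and 5 germ-free pregnant. Per the labels, pregnant animals were taken at gestation day 15, total RNA was extracted from snap-frozen tissue, and libraries were made with a non-stranded NEBNext Ultra RNA kit. The labels' protocols date the pregnancies differently: conventional matings lasted 1 night, whereas germ-free matings lasted several days and their gestation day was assumed, so gestational age was less certain in germ-free mice. Age labels, whose unit is not stated, ran from 70 to 77 in conventional and from 91 to 121 in germ-free mice. Age and microbiota status therefore did not overlap.

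The deposited table held estimated counts per gene, not scaled between libraries, in 53392 rows with versioned Ensembl identifiers. Per the submitters' processing notes, Salmon 0.11.3, edgeR 3.24.3 and the build GRCm38.p6 were used by the authors. The annotation release, the summing of transcripts to genes and the read layout were not given in the sources used here. Estimated counts divide reads that match several transcripts, so 14.7% to 26.3% of the deposited values per library were not whole. Genes of families with near-identical copies (Cyp2b, Cyp2c, Cyp3a, Mup, Sult3a, Ugt1a) are therefore uncertain individually. Reads of overlapping and antisense genes could not be told apart with this kit.

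Identifiers were matched to symbols with the GENCODE M21 tables, of which 97.7% matched with their version and 99.93% with or without it. Coordinates are 1-based positions of the GENCODE M21 gene models on GRCm38. Library totals were 18064491 to 30036912 estimated counts. The percentage of counts from mitochondrially encoded genes ran from 5.9% to 31.99%. Libraries of one group were compared by their counts over genes in 50 pairs, and the mean chi-square per gene was at least 36.1 in each pair, so no library was a repeat of another of its group. Libraries of different groups were not compared in this way. The labels describe the libraries as separate mice. P-values of single genes, and of list means and sums, set differences against the spread between mice. The camera test described below ranks a list's genes against the other genes. Fisher's exact test and its intervals take genes as units and do not measure the spread between mice. Floors cover counting error only.

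Estimated counts were rounded to whole numbers, and the absolute changes summed to 0.0083% of the counts. Genes were kept with the default filter of edgeR 4.0.16 (a minimum count of 10 and a total of 15), leaving 15928 genes. Libraries were scaled by TMM, and all 22 libraries were fitted in 1 quasi-likelihood model with 1 term per group. The 4 comparisons were pregnancy in conventional mice, pregnancy in germ-free mice, germ-free status in non-pregnant mice and germ-free status in pregnant mice. The interaction tested whether the pregnancy change differed between germ-free and conventional mice. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p of a gene comes from this edgeR fit. Levels are counts scaled to the effective library size (CPM), given as mean ± SD, and log2 fold changes are given ± their standard error. The standard error was derived from the F statistic and the fitted change. A prior count of 2 was used for the log2 CPM of single libraries. For a group with 0 counts, the fold was computed against a floor of 3 counts per library.

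A total of 36 gene lists were fixed before the data were examined. They covered drug-processing enzymes and transporters, bile acid, lipid and glucose metabolism, hormone signalling, sex-biased liver genes, immune responses, hepatocyte zones, and markers of other cell types. Of these, 35 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test was run with the correlation estimated from the data. Several lists share members: 16 of the 62 members of the cytochrome P450 list (58 of them tested) and 16 of the 21 female-biased genes stand in another list. Because random regroupings of the libraries also passed many lists at the preset correlation, the mean log2 CPM of each list per library was compared between groups with an exact two-sided permutation test. That test was chosen after seeing the data. Overlaps of calls were tested with Fisher's exact test, two-sided.

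The genes named were set by a rule fixed before the data were examined. For each comparison, the rule took the 5 higher and the 5 lower genes with the largest change among those with an official symbol, at least 5 CPM in the higher group and no overlap between the groups' libraries. It then took the 2 called members with the lowest adjusted p from each list, and 18 drug-processing genes whatever their test. For the interaction, it took up to 10 called genes. Chance alone separates 6 from 5 libraries completely in 0.433% of genes, 6 from 6 in 0.216% and 5 from 5 in 0.794%.

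The fitting steps were tested on simulated counts for the 15928 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. At 2-fold, edgeR recovered 49% of changed genes for pregnancy in conventional mice, 43% for pregnancy in germ-free mice, 59% for germ-free status in non-pregnant mice, 43% for germ-free status in pregnant mice and 27% for the interaction. At 4-fold, it recovered 82%, 76%, 87%, 82% and 72% in the same order. Unchanged genes called by edgeR numbered 4, 4, 6, 8 and 4 in that order. DESeq2 called more unchanged genes in the same simulations: 28, 25, 24, 26 and 22. Limma-voom with quality weights called 5, 1, 8, 7 and 2.

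The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, no low-count filter, a stricter filter (5 CPM in 5 libraries), a fit of only the groups compared, a replicate block, age as a covariate, and leaving out each library in turn. Age was centred within conventional and within germ-free mice, so that fit could not adjust the microbiota comparisons for their age gap. Fits without the farthest library of each group, fits without a pair of libraries that stood apart in list means (conventional pregnant replicate 2 and germ-free non-pregnant replicate 6), the permutation test of list means, and the sum over the Mup family were added after seeing the data. The fits without that pair kept germ-free non-pregnant replicate 2, the farthest library of its group. No library was left out of the main results. Results for some genes are not reported here. R 4.3.3 was used throughout.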

Results

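RNA was sequenced from the livers of 22 female C57BL/6 mice that differed in pregnancy and in microbiota status. Conventional mice carry an ordinary gut microbiota, and germ-free mice are raised without microorganisms. The groups were 6 conventional non-pregnant, 5 conventional pregnant, 6 germ-free non-pregnant and 5 germ-free pregnant mice, with pregnant mice labelled as taken at gestation day 15. In germ-free mice that day was assumed after matings of several days. Comparisons of germ-free with conventional pregnancy, the interaction included, may thus also compare gestational ages. Total estimated counts ranged from 18064491 to 30036912 per library. The series' title names the question as how the microbiome affects hepatic drug-processing genes during pregnancy. The microbiota comparisons also compare ages, since the age labels (unit not stated) were 70 to 77 in conventional and 91 to 121 in germ-free mice.

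In conventional mice, pregnancy went with higher expression of the prolactin receptor, the growth hormone receptor, ceruloplasmin and several Cyp3a genes, and with lower expression of bile acid and organic anion uptake carriers. Prlr, the prolactin receptor, rose from 227 ± 39.6 CPM (SD, n = 6) to 1460 ± 633 CPM (SD, n = 5), a log2 change of 2.69 ± 0.26 (edgeR adjusted p = 2.01e-07), and was higher in each of the 5 pregnant libraries than in any non-pregnant one. Ghr, the growth hormone receptor, rose by 2.40 ± 0.29. Cp, which encodes the copper carrier ceruloplasmin, rose by 2.67 ± 0.25. Cyp3a44, a cytochrome P450 higher in female than in male liver, rose by 3.89 ± 0.55, and Cyp2b13, another female-biased P450, fell by 3.64 ± 0.29. In all, 875 genes were higher and 561 lower among 15928 tested.

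Prlr (ENSMUSG00000005268.20) lies on chromosome 15 at 10177238 to 10349180 of GRCm38, and Ghr (ENSMUSG00000055737.12) on chromosome 15 at 3317760 to 3583492. Cp (ENSMUSG00000003617.16) lies on chromosome 3 at 19957054 to 20009145, and Cyp2b13 (ENSMUSG00000040583.8) on chromosome 7 at 26061497 to 26096197.

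Among genes with the largest changes in this comparison, Serpina16 stood at 9.15 ± 7.13 CPM in pregnant mice and 0.0105 ± 0.0257 CPM in non-pregnant mice, where 2 counts were seen over 6 libraries. Sult4a1, a sulfotransferase best known from brain, stood at 5.16 ± 3.74 CPM against 0.0116 ± 0.018 CPM, also from 2 counts. Sorcs3, a sorting receptor, rose by 7.33 ± 0.58 and Nptx1, a neuronal pentraxin, by 6.88 ± 0.64. Adgrf1, an adhesion G protein-coupled receptor, fell by 3.88 ± 0.56. Elovl3, a male-biased fatty acid elongase, fell by 3.59 ± 0.71. Mup11 and Mup12, major urinary protein genes with near-identical copies, both had lower levels: Mup11 fell by 3.63 ± 0.68 and Mup12 fell by 3.59 ± 0.80.

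Of 58 cytochrome P450 genes for drug metabolism tested in conventional mice, 9 rose and 13 fell with pregnancy (9 and 26 when adjusted over the list alone). Besides Cyp2b13, Cyp2c50 fell by 2.05 ± 0.18 and Cyp4a14, a fatty acid hydroxylase, by 1.40 ± 0.30. Cyp3a11, the main drug-metabolising Cyp3a enzyme of mouse liver, stood at 1610 ± 370 CPM against 2850 ± 333 CPM with no overlap between groups. It did not pass the test (adjusted p = 0.0966), although DESeq2 called it (adjusted p = 0.0329). The camera test placed the P450 list lower at the preset correlation (adjusted p = 1.84e-05), with adjusted p = 0.38 with an estimated correlation. Among 48 other phase I enzymes, 4 rose and 7 fell (6 and 7 adjusted over the list alone; list adjusted p = 0.0525), with Aldh1a7, an aldehyde dehydrogenase, up by 2.98 ± 0.19 and the carboxylesterase Ces1b down by 1.10 ± 0.16.

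Of 20 UDP-glucuronosyltransferase genes, 1 rose and 2 fell in the same mice (1 and 4 adjusted over the list alone), among them Ugt1a6b, which fell by 1.74 ± 0.19. That list passed lower at the preset correlation (adjusted p = 0.00875) but had adjusted p = 0.466 with an estimated correlation. Of 17 sulfotransferases, 3 rose and 3 fell, the same numbers as when adjusted over the list alone, with Sult3a2 up by 5.84 ± 0.67 (list adjusted p = 0.499). The sulfotransferase list had a median log2 change of -0.22, a mean of 0.18 and a test on the lower side, and the glutathione list likewise a median of -0.10, a mean of 0.22 and a test on the lower side. Of 25 glutathione conjugation genes, 5 rose and 4 fell (5 and 6 adjusted over the list alone; list adjusted p = 0.213); Gstp1 rose by 1.92 ± 0.35 and Gstt1 fell by 1.44 ± 0.22. Of 14 acetyl- and methyltransferases, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with the methyltransferase Inmt down by 1.43 ± 0.29. Its list test gave adjusted p = 0.0038 at the preset correlation and adjusted p = 0.466 with an estimated correlation.

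Of 19 uptake transporters, 1 rose and 6 fell with pregnancy in conventional mice (1 and 7 adjusted over the list alone). Slc10a1, the main sodium-dependent bile acid carrier of hepatocytes, fell by 1.27 ± 0.26 and Slco1a4, an organic anion carrier, by 1.72 ± 0.34. The mean log2 CPM of this list was lower by 0.38 in pregnant mice (exact permutation test, adjusted p = 0.0189), whereas camera gave adjusted p = 0.00349 at the preset correlation and adjusted p = 0.354 with an estimated correlation. Of 19 efflux transporters, 4 fell, including the sterol exporters Abcg5 by 1.30 ± 0.23 and Abcg8 by 0.94 ± 0.20, and none rose (1 and 4 adjusted over the list alone; adjusted p = 0.0304 at the preset correlation, adjusted p = 0.354 with an estimated correlation). Of 14 genes of bile acid synthesis, 3 fell, among them Cyp39a1 by 1.40 ± 0.31 (4 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.532 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 change of 0.33 ± 0.45 (adjusted p = 0.745). Of 20 xenobiotic and bile acid sensors, 2 rose and none fell, the same numbers as when adjusted over the list alone (list adjusted p = 0.968). Nfe2l2, a regulator of antioxidant genes, rose by 0.62 ± 0.14.

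Of 15 growth hormone and prolactin signalling genes, 3 rose and 1 fell in pregnant conventional mice (5 and 1 adjusted over the list alone), and the list mean was higher by 0.47 in log2 CPM (exact permutation test, adjusted p = 0.0189). Camera gave adjusted p = 0.0212 for it at the preset correlation and adjusted p = 0.223 with an estimated correlation. Of 21 female-biased liver genes, 7 rose and 1 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.127), and of 15 male-biased genes 2 rose and 5 fell (2 and 7 adjusted over the list alone). The mean of the male-biased list was lower by 0.99 (exact permutation test, adjusted p = 0.0189); camera gave adjusted p = 0.0293 and adjusted p = 0.619 with an estimated correlation. Of 18 pericentral hepatocyte genes, 10 fell and none rose (13 and 1 adjusted over the list alone), with Lect2 down by 1.60 ± 0.18 and Oat, ornithine aminotransferase, by 1.55 ± 0.30. The pericentral list mean was lower by 0.75 (exact permutation test, adjusted p = 0.0189); camera gave adjusted p = 1.16e-08 and adjusted p = 0.223 with an estimated correlation. Of 17 periportal genes, 3 rose and 5 fell (3 and 8 adjusted over the list alone; adjusted p = 0.0252, and adjusted p = 0.639 with an estimated correlation).

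For lipid and glucose metabolism in conventional mice, 1 of 24 cholesterol synthesis genes fell with pregnancy (1 adjusted over the list alone; list adjusted p = 0.00349, and adjusted p = 0.715 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, 3 rose and 4 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.102), with the desaturase Scd1 down by 1.55 ± 0.26 and the desaturase Fads1 up by 1.25 ± 0.21. Of 30 PPAR-alpha target genes, 5 rose and 3 fell (8 and 5 adjusted over the list alone; list adjusted p = 0.193). Of 18 glucose metabolism genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; list adjusted p = 0.0539), among them Pck1, an enzyme of gluconeogenesis, by 1.00 ± 0.23. Of 19 clock genes, Arntl alone was called, higher by 2.66 ± 0.77 (1 adjusted over the list alone; list adjusted p = 0.0989), and it lost its call in 7 of 11 fits that each left out 1 library (highest adjusted p = 0.105). The clock list had a median of -0.27, a mean of 0.04 and a test on the lower side.

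Immune and proliferation genes in pregnant conventional mice were set in part by 1 library, conventional pregnant replicate 2, in which the acute phase genes Saa1 and Saa2 reached 2050 and 2160 CPM against at most 62.2 and 43.5 CPM in the other 21 libraries. Of 38 cell cycle genes, 17 rose and 1 fell (32 and 1 adjusted over the list alone; adjusted p = 1.82e-07, and adjusted p = 0.589 with an estimated correlation), and Mki67, a proliferation marker, changed by 2.56 ± 0.56, or by 1.39 without that library (adjusted p = 0.0528). The cell cycle list mean was 4.09 log2 CPM in that library and 1.37 to 1.87 in the rest of its group. Of 30 acute phase genes, 15 rose and 2 fell (20 and 3 adjusted over the list alone; adjusted p = 7.8e-07, and adjusted p = 0.38 with an estimated correlation). Of 35 interferon response genes, 5 were called higher and none lower (6 adjusted over the list alone; adjusted p = 0.0373, and adjusted p = 0.738 with an estimated correlation). The interferon call ended in 4 more fits that each left out 1 library, conventional non-pregnant replicate 3, 5 or 6 or conventional pregnant replicate 1 (highest of the 4 adjusted p = 0.124). The chemokine gene Cxcl10 changed by 4.67 ± 1.08, or by -0.35 without the library, and the interferon list turned in direction without it (adjusted p = 0.394). Of 6 neutrophil markers, Il1b and Prtn3 were called higher (4 adjusted over the list alone; list adjusted p = 0.189) and lost their calls without that library, at log2 changes of 0.86 and -1.60. Prtn3 also lost its call without conventional non-pregnant replicate 2, 3, 4 or 5 (adjusted p of 0.0698, 0.0656, 0.0733 and 0.0758).

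Few markers of other cell types were called with pregnancy in conventional mice. No MHC class II gene of 9 (adjusted p = 0.213), endothelial marker of 16 (adjusted p = 0.495), B and plasma cell marker of 12 (adjusted p = 0.732, with a median of -0.02, a mean of 0.06 and a test on the lower side), T and NK cell marker of 15 (adjusted p = 0.608), adipose or muscle marker of 7 (adjusted p = 0.117) or mitochondrially encoded gene of 13 was called by edgeR, over all genes or adjusted over the list alone. The mitochondrial list passed lower at the preset correlation (adjusted p = 0.0188) with adjusted p = 0.715 with an estimated correlation. Slc40a1, an iron exporter, was the 1 of 17 Kupffer cell markers called, higher by 0.53 ± 0.12 (1 adjusted over the list alone; list adjusted p = 0.0525). Of 15 stellate cell markers, Col3a1 rose by 1.07 ± 0.23 and Lrat, which stores retinol as esters, fell by 1.21 ± 0.23 (2 and 2 adjusted over the list alone; list adjusted p = 0.968, with a median of -0.03, a mean of 0.15 and a test on the higher side). Of 10 cholangiocyte markers, Spp1 fell by 1.07 ± 0.24 (1 and 1 adjusted over the list alone; list adjusted p = 0.334). Of 13 erythroid markers, Alas2 and Slc4a1 rose by 1.45 ± 0.28 and 2.74 ± 0.61 (8 and 1 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.476 with an estimated correlation). Of 23 handling and stress genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.225). Only 2 exocrine pancreas markers were measured, too few to test, and neither was called over all genes, although 1 was lower when adjusted over the list alone.

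With the 2 conventional groups fitted on their own, 497 genes were higher, and DESeq2 called 896 lower. Of 16 lists called at the preset correlation in this comparison, none was called with an estimated correlation (lowest adjusted p = 0.223). The exact permutation test of list means passed for 4 of the 35 lists (13 at an unadjusted p under 0.05), the uptake, growth hormone and prolactin, male-biased and pericentral lists. It did not pass for the P450 (adjusted p = 0.499), glucuronosyltransferase (0.0758), acetyl- and methyltransferase (0.0874), efflux (0.0631), bile acid (0.162) and cholesterol lists (0.0874). Nor did it for the cell cycle (0.0874), acute phase (0.0833), interferon (0.714), periportal (0.491), erythroid (0.0631) and mitochondrial lists (0.421). At the preset correlation, the bile acid, periportal and mitochondrial lists also lost their calls without conventional pregnant replicate 2 (adjusted p of 0.196, 0.112 and 0.145), and the efflux, male-biased, growth hormone and prolactin, bile acid and periportal lists without conventional non-pregnant replicate 6 (0.0992, 0.0636, 0.0571, 0.0621 and 0.15). The efflux, male-biased and periportal lists lost theirs without conventional pregnant replicates 5, 1 and 4 in turn (0.0579, 0.119 and 0.102), and the mitochondrial list without conventional non-pregnant replicate 1 or 4 (0.0643 and 0.0639).

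**Figure D1:**
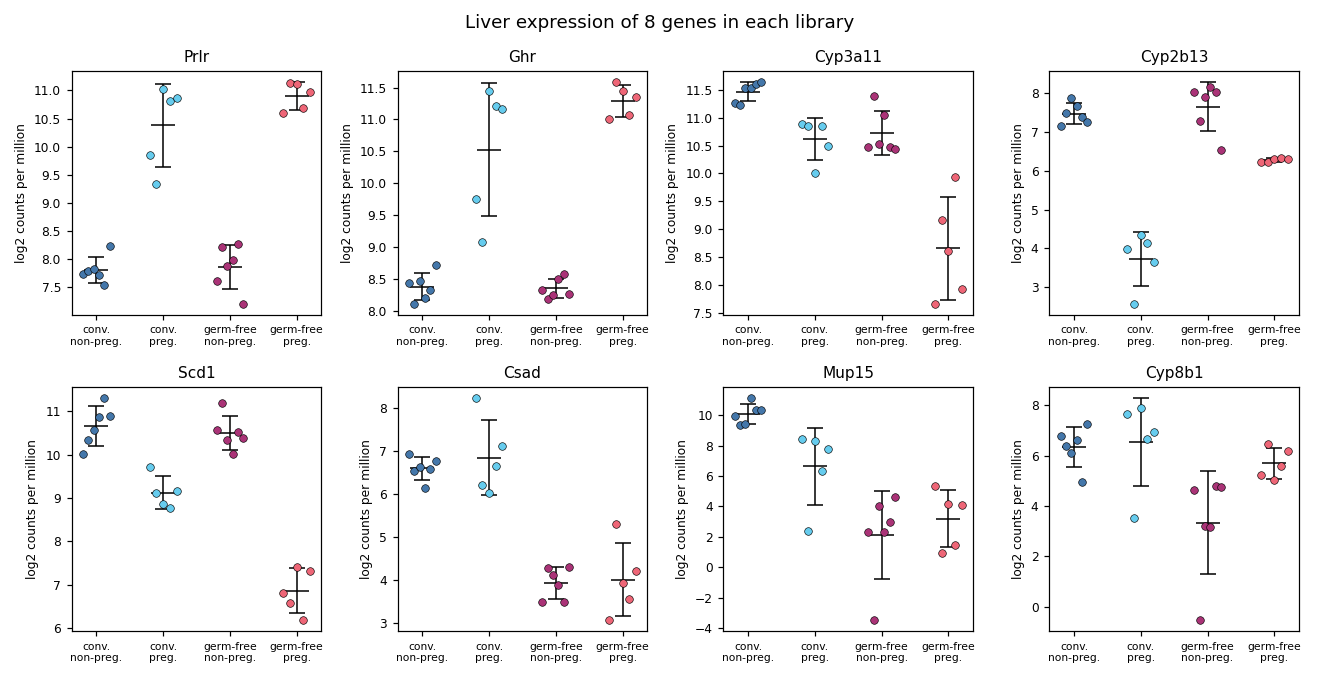
Log2 CPM (y axis) of 8 genes in each of the 22 libraries, by group (x axis). Points are libraries, spread left to right by replicate number, and black bars are the mean ± SD; Prlr separates pregnant from non-pregnant mice, and Csad separates germ-free from conventional mice.

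In germ-free mice, pregnancy raised the same receptors and Cyp3a genes and lowered the desaturase Scd1 and Cyp3a11. Prlr rose from 239 ± 60.6 CPM (SD, n = 6) to 1940 ± 322 CPM (SD, n = 5), a log2 change of 3.02 ± 0.26 (edgeR adjusted p = 3.94e-08). Ghr rose by 2.95 ± 0.30, Cp by 3.17 ± 0.25 and Aldh1a7 by 3.10 ± 0.19. Scd1, which makes monounsaturated fatty acids, fell by 3.62 ± 0.29, and Cyp3a11 by 1.88 ± 0.32 (adjusted p = 0.000253). In all, 1139 genes were higher and 574 lower among 15928 tested.

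Abca17, an ABC transporter gene, had 0 counts in germ-free non-pregnant mice and 7.64 ± 3.49 CPM in germ-free pregnant mice, at least 58-fold higher against a floor of 3 counts per library. Serpina16 rose by 8.20 ± 0.84 and Sult3a2 by 7.75 ± 0.77. Cyp3a41b and Cyp3a16, which share reads with their paralogs, rose by 7.38 ± 0.98 and 6.92 ± 0.82. Hamp, which encodes the iron hormone hepcidin, fell by 4.02 ± 0.84. Adgrf1 fell by 3.85 ± 0.55, Adam11, a member of the ADAM family, fell by 3.98 ± 0.66 and Cyp26b1, which breaks down retinoic acid, by 3.78 ± 0.60.

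Of 58 P450 genes tested in germ-free mice, 12 rose and 8 fell with pregnancy (15 and 12 adjusted over the list alone), and the list mean was higher by 0.30 (exact permutation test, adjusted p = 0.0379). Camera gave adjusted p = 0.891 for this list, whose median log2 change was -0.14 and mean 0.24. Among other phase I enzymes, 6 rose and 8 fell, with the flavin monooxygenase Fmo5 down by 2.00 ± 0.24 (6 and 10 adjusted over the list alone). Among glucuronosyltransferases, 3 rose and 3 fell (3 and 4 adjusted over the list alone). Among sulfotransferases, 3 rose and 3 fell (5 and 5 adjusted over the list alone). Slco1a4 and Slc10a1 fell by 1.68 ± 0.34 and 1.08 ± 0.26, and the efflux transporter Abcc3 by 2.59 ± 0.43. Slc22a7, an organic anion transporter, rose by 1.77 ± 0.34. Nr0b2, a repressor induced by the bile acid receptor, fell by 1.27 ± 0.34 but did not pass without germ-free non-pregnant replicate 2 or germ-free pregnant replicate 5 (adjusted p of 0.0541 and 0.0558), while Cyp7a1 (0.42 ± 0.45, adjusted p = 0.624) and Cyp8b1 (1.77 ± 0.62, adjusted p = 0.0695) did not pass.

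Of 30 acute phase genes, 14 rose and 1 fell with pregnancy in germ-free mice (19 and 2 adjusted over the list alone), and the list mean was higher by 0.78 (exact permutation test, adjusted p = 0.0379). Camera gave adjusted p = 5.9e-10 for it at the preset correlation and adjusted p = 0.262 with an estimated correlation. Of 13 erythroid markers, 7 rose, including Slc4a1, the red cell anion exchanger, by 4.53 ± 0.62 and Alas2, the erythroid enzyme of haem synthesis, by 1.83 ± 0.28 (8 adjusted over the list alone). The erythroid list mean was higher by 1.45 (exact permutation test, adjusted p = 0.0379); camera gave adjusted p = 2.14e-05 and adjusted p = 0.262 with an estimated correlation. The mean of the growth hormone and prolactin list was higher by 0.39 (exact permutation test, adjusted p = 0.0379), with 4 of 15 members higher (4 adjusted over the list alone) and a median log2 change of 0; camera gave adjusted p = 0.0573 and adjusted p = 0.262 with an estimated correlation. Female-biased genes passed camera higher at the preset correlation (adjusted p = 0.0328), with adjusted p = 0.903 with an estimated correlation, and lost that call without germ-free non-pregnant replicate 3 or 6 (adjusted p of 0.0502 and 0.101). Their list mean did not pass the exact permutation test (adjusted p = 0.0884), which 4 of 35 lists passed in germ-free mice (6 at an unadjusted p under 0.05). Of 38 cell cycle genes, Ccnd1 alone was called, lower by 1.03 ± 0.25 (1 adjusted over the list alone). Krt19, a bile duct keratin, changed by 3.10 ± 0.70, or by 0.69 without germ-free pregnant replicate 2 (adjusted p = 0.242). With quality weights limma-voom called 1818 genes higher and 1209 lower, and DESeq2 called 876 lower.

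Between conventional and germ-free mice, 577 genes were called higher with pregnancy in both, where 62.6 would be shared by independent sets (Fisher's exact test, odds ratio 49.9, 95% interval 42.2 to 59.1). Another 291 were called lower in both, against 20.2 (odds ratio 57.3, 46.7 to 70.8). All 868 genes called in both had the same sign, as did 96% of the 2281 genes called in either. Across 15928 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.61 and a Spearman correlation of 0.50. The comparisons share no library.

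**Figure D2:**
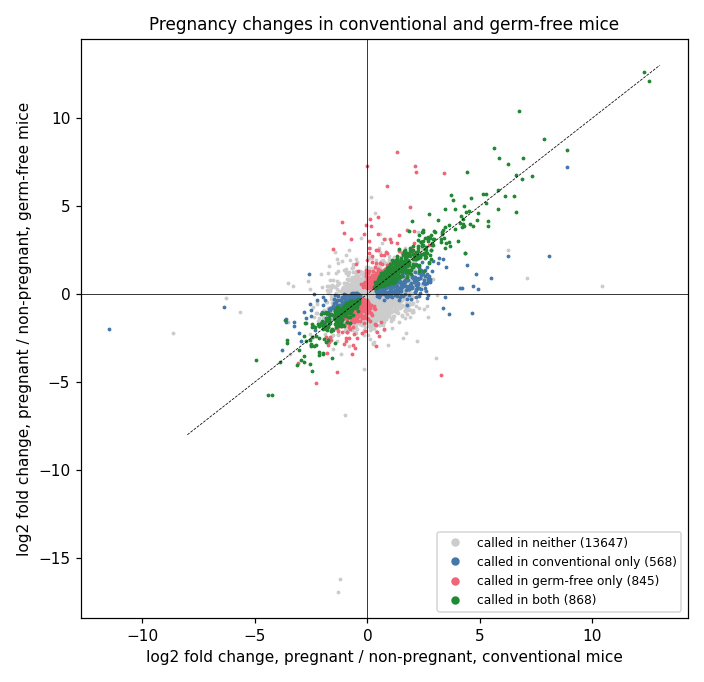
Log2 fold change with pregnancy in conventional mice (x axis) against that in germ-free mice (y axis) for 15928 genes, coloured by the comparison in which each was called, with the dashed line at equal change. The 868 genes called in both (green) lie where both changes have the same sign.

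Germ-free non-pregnant mice differed from conventional ones in few genes, chiefly lower Csad, Sult5a1 and major urinary protein genes and higher Cd36, Krt23 and Serpina7. Csad, which makes the taurine precursor hypotaurine, fell from 98.7 ± 17.2 CPM (SD, n = 6) to 15.6 ± 3.87 CPM (SD, n = 6), a log2 change of -2.66 ± 0.36 (edgeR adjusted p = 0.0012). Mup15 and Mup17 fell by 6.94 ± 1.04 and 5.96 ± 0.88, and Mup11 by 3.21 ± 0.62. Cd36, a fatty acid carrier, rose by 1.38 ± 0.19, Krt23, a keratin, by 2.54 ± 0.34, and Serpina7, which encodes thyroxine-binding globulin, by 2.80 ± 0.51. In all, 14 genes were higher and 11 lower among 15928 tested.

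Csad (ENSMUSG00000023044.2) lies on chromosome 15 at 102176999 to 102204724, and Mup15 (ENSMUSG00000096674.1) on chromosome 4 at 61435790 to 61439743. Sult5a1, a sulfotransferase, fell by 2.28 ± 0.39 and was the only sulfotransferase called of 17 (1 and 4 adjusted over the list alone). Noct, a clock-driven gene, rose by 1.51 ± 0.30, Tsc22d3, a glucocorticoid-induced gene, by 1.15 ± 0.20, and the heat shock gene Hspa1b by 1.87 ± 0.36. None of 58 P450 genes was called by edgeR over all genes (1 higher adjusted over the list alone), and Cyp3a11 differed by -0.71 ± 0.29 (adjusted p = 0.639). Cyp8b1, which sets the ratio of cholic acid to other bile acids, stood at 16.2 ± 11.5 CPM against 89.8 ± 40.2 CPM with no overlap between groups, and did not pass (adjusted p = 0.133).

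None of the 24 cholesterol synthesis genes was called over all genes in germ-free non-pregnant mice, but 20 were lower when adjusted over the list alone, and the median log2 difference was -0.97. Camera placed the list lower at the preset correlation (adjusted p = 3.84e-38), with adjusted p = 0.0725 with an estimated correlation. Its mean was 5.93 ± 0.84 log2 CPM (SD, n = 6) against 7.00 ± 0.19 (SD, n = 6), an exact permutation p of 0.00433 that became 0.0505 over the 35 lists. The glucose metabolism list (5 of 18 higher adjusted over the list alone) and the handling and stress list (4 of 23) were placed higher by camera, with adjusted p = 0.0014 and 4.04e-05 at the preset correlation and adjusted p = 0.328 for both with an estimated correlation. Their means were higher by 0.35 and 0.46, with exact permutation p of 0.00216 and 0.00433 and adjusted p of 0.0505 for both, and 0 of the 35 lists passed that test (4 at an unadjusted p under 0.05). With 6 against 6 libraries, 0.00216 is the lowest p this test can give. A single list at that p cannot pass over 35 lists on its own. Male-biased genes were placed lower (adjusted p = 0.00142), with adjusted p = 0.662 with an estimated correlation, although the 1 of 15 called over the list alone was higher. The other phase I, sulfotransferase, bile acid, Kupffer cell and mitochondrially encoded lists had adjusted p of 0.0269, 0.0385, 0.0106, 0.0315 and 0.0269 at the preset correlation. Their adjusted p were 0.928, 0.703, 0.703, 0.928 and 0.928 with an estimated correlation. Germ-free non-pregnant replicate 6 stood low for the sulfotransferase mean, at 2.19 log2 CPM against 3.63 to 4 in the rest of its group. Replicate 2 stood low for the bile acid mean, at 5.84 against 6.54 to 6.86.

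Leaving out single libraries moved these counts. Higher genes numbered 7 without conventional non-pregnant replicate 1, 5 without replicate 2, 5 without replicate 3, 8 without replicate 4 and 7 without replicate 6, and 7 and 6 without germ-free non-pregnant replicates 3 and 4. Lower genes numbered 6, 5, 7, 7 and 6 without conventional non-pregnant replicates 1, 3, 4, 5 and 6, and 6, 5 and 5 without germ-free non-pregnant replicates 1, 3 and 4. The calls of Csad, Mup15, Mup17, Cd36, Krt23, Sult5a1 and Tsc22d3 held in each such fit, while Mup11, Noct, Hspa1b and Serpina7 lost theirs in 8, 7, 7 and 4 of the 12. DESeq2 called 55 genes higher and 62 lower, and limma-voom 41 and 51.

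In pregnant mice, germ-free status went with lower Cyp3a11, Scd1 and Csad and higher Cyp2b13 and several Cyp2c genes. Cyp3a11 stood at 475 ± 313 CPM (SD, n = 5) against 1610 ± 370 CPM in conventional pregnant mice (SD, n = 5), a log2 change of -1.76 ± 0.32 (edgeR adjusted p = 0.0222). Cyp2b13 rose by 2.43 ± 0.28, Cyp2c38 by 1.43 ± 0.26, Cyp2c39 by 1.37 ± 0.28, Cyp2c67 by 1.15 ± 0.22 and Cyp2c50 by 0.95 ± 0.17. Scd1 fell by 2.23 ± 0.28 and Csad by 2.87 ± 0.40. In all, 13 genes were higher and 8 lower among 15928 tested.

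Cyp3a11 (ENSMUSG00000056035.8) lies on chromosome 5 at 145854426 to 145879964, and Scd1 (ENSMUSG00000037071.2) on chromosome 19 at 44394455 to 44407879. Of the 58 P450 genes, 6 were higher and 1 lower in germ-free pregnant mice (12 and 3 adjusted over the list alone), and camera placed the list higher (adjusted p = 5.73e-09, and adjusted p = 0.201 with an estimated correlation). The P450 list mean was higher by 0.30, with an exact permutation p of 0.00794 and adjusted p = 0.139, and 0 of the 35 lists passed that test in pregnant mice (5 at an unadjusted p under 0.05). With 5 against 5 libraries, 0.00794 is the lowest p this test can give. A list at that p cannot pass over 35 lists unless several others reach it too. That the P450 list did not pass therefore does not argue against it. Retreg1, a receptor for turnover of the endoplasmic reticulum, rose by 1.14 ± 0.19, Pck1 by 1.23 ± 0.24 and the glucuronosyltransferase Ugt1a9 by 1.09 ± 0.22. Sult5a1 fell by 2.41 ± 0.44, Apoa4, an apolipoprotein, by 1.18 ± 0.22, the carboxylesterase Ces2a by 1.02 ± 0.18 and Sult4a1 by 3.62 ± 0.70. The bile acid carrier Slc10a1 (-0.04 ± 0.27, adjusted p = 0.982) and Cyp7a1 (0.05 ± 0.47, adjusted p = 0.986) did not pass.

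No gene of the interferon, MHC class II, cell cycle, Kupffer cell, T and NK cell or neutrophil lists was called by edgeR over all genes in this comparison, though 23 of 35 interferon, 8 of 9 MHC class II, 4 of 6 neutrophil and 1 of 15 T and NK cell genes were lower when adjusted over the list alone. Camera placed these 6 lists lower at the preset correlation, with adjusted p of 1.49e-15, 0.00126, 0.000117, 3.6e-05, 0.00146 and 0.00576 in that order. With an estimated correlation the adjusted p were 0.32, 0.469, 0.536, 0.462, 0.488 and 0.462. Without conventional pregnant replicate 2, only the interferon list was still placed lower (adjusted p = 3.2e-06), and the cell cycle list turned in direction (adjusted p = 0.367). Mitochondrially encoded genes were placed higher (adjusted p = 1.15e-10, and adjusted p = 0.32 with an estimated correlation), with list means of 13.03 ± 0.66 log2 CPM against 11.92 ± 0.77 (exact permutation test, adjusted p = 0.278).

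Camera placed 13 other lists apart in pregnant mice at the preset correlation and none with an estimated one. Glucose metabolism (adjusted p = 2.58e-05), erythroid markers (6.94e-06), pericentral genes (3.6e-05) and acetyl- and methyltransferases (0.000135) were placed higher and fatty acid and triglyceride synthesis lower (0.00126), each also with any 1 library left out. With an estimated correlation these 5 had adjusted p of 0.201, 0.201, 0.338, 0.32 and 0.457. Cholangiocyte markers (0.0023 and 0.457 with an estimated correlation) and adipose and muscle markers (0.0123 and 0.469) were placed higher, the first not without germ-free pregnant replicate 2 (0.224) and the second not without replicate 3 or 5 (0.104 and 0.12). Endothelial markers (0.00202 and 0.469) and cholesterol synthesis (0.00972 and 0.646) were placed lower. The endothelial call was lost without conventional pregnant replicate 5 (0.11) or germ-free pregnant replicate 3 (0.0651), and the cholesterol call without conventional pregnant replicate 1 or 5 (0.213 and 0.062) or germ-free pregnant replicate 2 or 4 (0.521 and 0.0784). Acute phase genes (0.00594 and 0.522, with a median of 0.21 and a mean of -0.35) were placed higher, but not without conventional pregnant replicate 1, 4 or 5 (0.213, 0.113 and 0.062). Glucuronosyltransferases (0.0489 and 0.488, with a median of 0.12 and a mean of -0.01) were placed higher, but not without conventional pregnant replicates 2 to 5 (0.291, 0.0558, 0.0554 and 0.075) or germ-free pregnant replicates 3 to 5 (0.104, 0.0783 and 0.0962). Clock genes (0.0396 and 0.462, with a median of 0.14 and a mean of -0.02) were placed higher, but not without conventional pregnant replicate 1 or 2 (0.087 and 0.627) or germ-free pregnant replicate 4 or 5 (0.0506 and 0.095). Periportal genes (0.0396 and 0.536) were placed higher, but not without conventional pregnant replicate 2, 4 or 5 (0.389, 0.278 and 0.0558) or germ-free pregnant replicate 2 (0.515).

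Fitting the pregnant groups alone left 2 genes higher and 3 lower, with Csad at adjusted p = 0.111 and Cyp3a11 at 0.265, while DESeq2 called 64 and 44. Leaving out conventional pregnant replicate 2, 4 or 5 left 8, 4 or 4 higher, leaving out germ-free pregnant replicate 3, 4 or 5 left 7, 2 or 4, and leaving out conventional pregnant replicate 3 gave 20. Lower genes numbered 3 and 2 without conventional pregnant replicates 4 and 5, and 5, 3 and 2 without germ-free pregnant replicates 3, 4 and 5. Cyp3a11 lost its call without conventional pregnant replicate 4 or 5 or germ-free pregnant replicate 3 or 5 (adjusted p of 0.0582, 0.0556, 0.0692 and 0.074). Only Cyp2b13, Scd1 and Csad among the genes named for this comparison kept their calls in each of the 10 fits that left out 1 library, and the other calls ended in at least 1 of the 10.

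**Figure D3:**
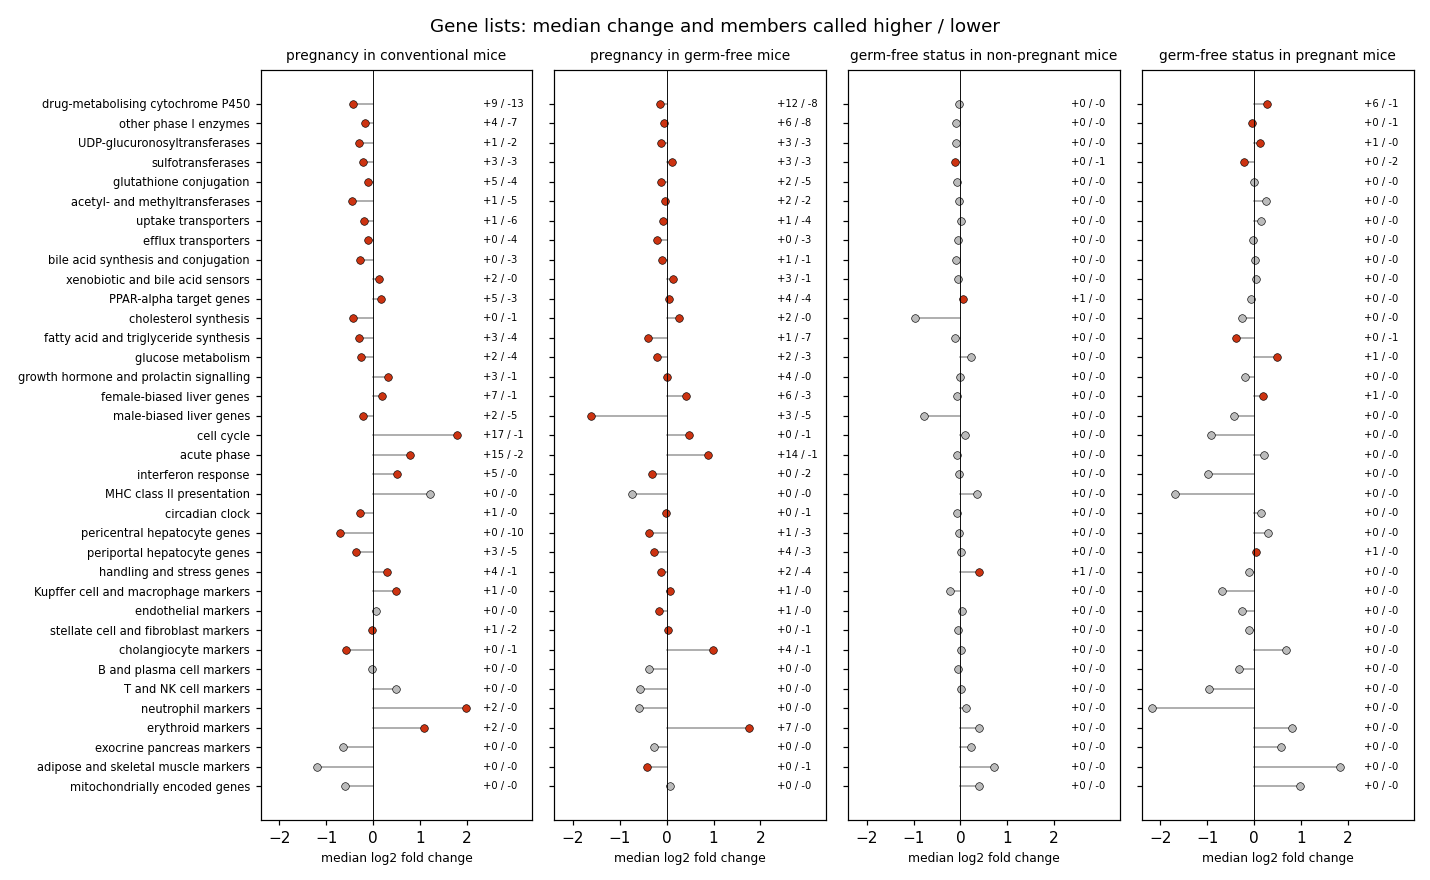
Median log2 fold change (x axis) of the 36 gene lists (y axis) in the 4 comparisons. Red points are lists with at least 1 member called, grey points lists with none, and the figures at the right of each panel give the members called higher (+) and lower (-).

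Across both microbiota comparisons, 5 genes were called in non-pregnant and in pregnant mice, all with the same sign. Csad, Sult5a1 and Apoa4 were lower, and 1810053B23Rik and Proser2 were higher. Apoa4 in non-pregnant mice and the 2 higher genes were chosen after their values were seen, because the shared set was small. Sharing was 2 higher genes against 0.0114 for independent sets and 3 lower genes against 0.00552 (Fisher's exact test, p = 5.57e-05 and 1.37e-08). Over 15928 genes, the Pearson correlation of log2 changes was 0.18.

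The pregnancy change itself did not differ between germ-free and conventional mice for any gene at the threshold. Cyp2b13 came closest, with a log2 difference of 2.16 ± 0.37 (edgeR adjusted p = 0.0717): it fell by 3.64 in conventional and by 1.47 in germ-free pregnancy. Scd1 had a difference of -2.06 ± 0.36 (adjusted p = 0.0717), falling by 1.55 and by 3.62. Cyp3a11 had a difference of -1.06 ± 0.43 (adjusted p = 0.863), so its larger fall in germ-free pregnancy is not shown to be a difference. Each conventional pregnant library (1030 to 1880 CPM) was also below every conventional non-pregnant one (2400 to 3190 CPM) for this gene. By edgeR 0 genes were called, with 903 at an unadjusted p under 0.05 where chance gives 796, while DESeq2 called 2 higher and 5 lower and limma-voom 1 and 1. Leaving out conventional pregnant replicate 1 gave 1 higher and 1 lower gene, and leaving out conventional pregnant replicate 2 or 3 or germ-free non-pregnant replicate 6 gave 1 higher. Of 35 lists, 21 passed camera at the preset correlation, led by cholesterol synthesis, which was placed higher (adjusted p = 6.49e-11), and none passed with an estimated correlation (lowest adjusted p = 0.373).

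**Figure D4:**
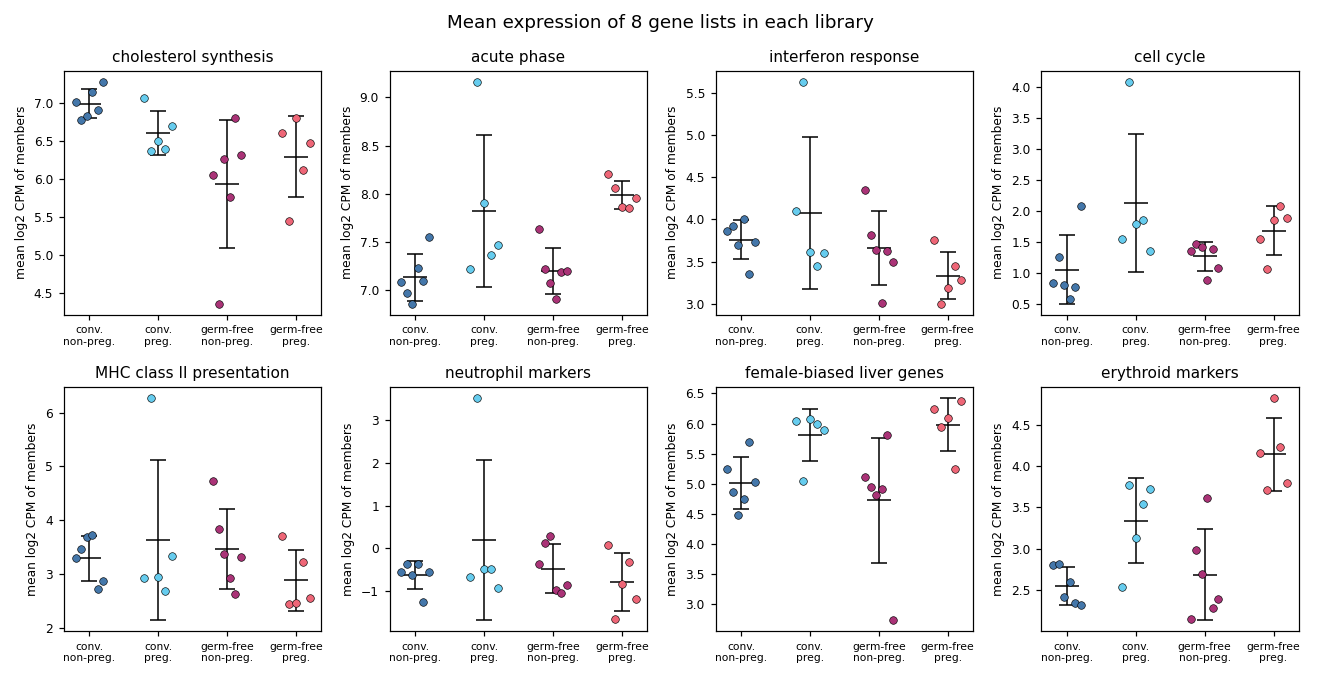
Mean log2 CPM of the members of 8 gene lists (y axis) in each of the 22 libraries, by group (x axis). Points are libraries, spread left to right by replicate number, and black bars are the mean ± SD; conventional pregnant replicate 2 is the highest point of its group for the interferon, cell cycle, MHC class II and neutrophil lists.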

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

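The tests on conventional pregnant replicate 2 were chosen only after the results they bear on were seen. Of 652 groups of libraries tested with Dixon's test for a highest or lowest library that stands apart from the rest of its group, 80 had one, where chance gives about 1 in 20 groups, or 33 here. Of these, 23 were conventional pregnant replicate 2 and 23 germ-free non-pregnant replicate 2. The tests were not independent, since lists and some of their members were both tested. Many of the genes were also named for their calls in these data. The 33 is therefore only a rough guide. Values below are the log2 CPM of the library that stood apart, or the mean log2 CPM of a list's members.

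The 6 immune and proliferation lists that were lower in germ-free than in conventional pregnant mice rested largely on conventional pregnant replicate 2, since 1 of 6 was still placed lower without it. White blood cells mixed into the tissue, with no change in hepatocytes, are argued against by Saa1 and Saa2, made mainly by hepatocytes, of which the smaller ratio to the highest of the other 21 libraries was 32.9. An inflammatory state of that mouse may account for the pattern, but no biological explanation was tested.

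In conventional pregnant replicate 2, the cell cycle list stood high at 4.09, MHC class II at 6.27, T and NK cell markers at 2.04, neutrophil markers at 3.51, handling and stress genes at 4.92 and cholangiocyte markers at 2.60. Glucuronosyltransferases stood low at 5.16, sulfotransferases at 2.95, uptake transporters at 4.62, bile acid synthesis at 5.64 and female-biased genes at 5.04. Among single genes, Mki67 stood high at 5.99, Nusap1, a spindle protein, at 3.69, Cxcl10 at 8.43, Col3a1 at 6.73 and Prtn3 at 4.72. Slc27a5, a bile acid ligase, stood low at 7.45, Cyp7a1 at 4.16, Cyp8b1 at 3.52, Ugt1a1 at 7.99, Cyp2c38 at 3.47, Ces2a at 6.91 and Tsc22d3 at 4.17.

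In germ-free non-pregnant replicate 2, uptake transporters stood low at 4.88, bile acid synthesis at 5.84 and pericentral genes at 5.17. Among its genes, the P450s Cyp2c50 stood low at 9.04, Cyp1a2 at 8.37, Cyp2c67 at 5.90, Cyp2d40 at 4.14 and Cyp8b1 at -0.53. The carboxylesterase Ces1b stood low at 5.95, Slc10a1 at 7.53, Nr1i3 at 6.70 and Nr1h4 at 5.26. Tm7sf2 stood low at 5.72, Elovl3 at -1.86, Mup15 at -3.47 and Mup17 at -0.53. Ciart stood low at 1.27, Axin2 at 2.23 and Hspa1b at 2.39. In contrast, Abcg5 stood high at 7.74, Arntl at 1.38 and Adam11 at 4.58.

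In germ-free non-pregnant replicate 6, sulfotransferases stood low at 2.19 and female-biased genes at 2.74, and Mup20 stood high at 8.55. Nusap1 stood low at -0.83 in germ-free non-pregnant replicate 4, and Retreg1 at 6.09 in replicate 3. In conventional non-pregnant replicate 6, periportal genes stood high at 8.75, Itih4 at 10.94, Aldh1b1 at 7.04, Slc40a1 at 7.09 and Abcb11 at 9.41. In conventional non-pregnant replicate 5, neutrophil markers stood low at -1.26, Gbp6 at 3.38 and Lrat at 3.26. Serpina16 stood high there at -2.71 against -3.47 in the rest of its group, values near the floor. Ifi44 stood high at 3.10 in conventional non-pregnant replicate 4 and Abca17 at -1.60 in replicate 2.

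In germ-free pregnant replicate 2, periportal genes stood high at 8.84, cholangiocyte markers at 4.99, Krt19 at 5.97 and Ces2a at 6.98, and Cyp39a1 stood low at 2.45. In germ-free pregnant replicate 1, Elovl3 stood high at 0.25 and Lect2 at 6.59, and Itih4 stood low at 12.18, Cyp2c29 at 8.92 and Retreg1 at 6.53. The growth hormone and prolactin list stood low at 5.32 in germ-free pregnant replicate 5, and Cyp7a1 stood high at 7.95 in replicate 3. Adipose and muscle markers stood high at -0.63 in conventional pregnant replicate 5 and Cyp4a14 at 9.12 in replicate 1. Ces1b stood low at 5.29 in conventional pregnant replicate 5 and Crat at 5.27 in replicate 4. Total estimated counts stood high in conventional non-pregnant replicate 5, at 30036912, and in germ-free non-pregnant replicate 1, at 23921979.

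The pregnancy change of 21 lists differed between germ-free and conventional mice by camera on the interaction at the preset correlation, and none differed with an estimated correlation (lowest adjusted p = 0.373). Lists with a higher change in germ-free mice were P450 genes (adjusted p = 2.87e-10), cholesterol synthesis (6.49e-11), pericentral genes (2.76e-05), mitochondrially encoded genes (0.000287) and acetyl- and methyltransferases (0.00245). Cholangiocyte and erythroid markers had adjusted p = 0.00539 each, uptake transporters and female-biased genes 0.00966 each. Glucuronosyltransferases had 0.0132, bile acid synthesis 0.0146, clock genes 0.0225, periportal genes 0.0238 and sulfotransferases 0.0329. Lists with a lower change were interferon response (4.04e-10), cell cycle (2.3e-06), MHC class II (0.00028), handling and stress (0.000456), endothelial markers (0.00105), T and NK cell markers (0.00107) and neutrophil markers (0.00287). Without conventional pregnant replicate 2, 9 of the 21 still differed, and of the lower ones the interferon (0.00305) and endothelial lists (0.000123) did.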

How the results depend on the processing

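Fits without the farthest library of each group, fits without conventional pregnant replicate 2 and germ-free non-pregnant replicate 6, and the overlaps with 1 library left out were chosen after seeing the data. No gene called under another setting had the opposite direction to its call in the results above. Of the counts under other settings, 209 were within 1.5 times the reported value and 73 were not. For named genes 4781 values kept their side of the threshold, 245 fell short of it, 33 newly passed and 7 turned in direction. For list tests the numbers were 2915, 269, 128 and 13. A turn was counted only where the result above or the other setting passed. Values that passed in neither may have turned uncounted. The cause was not tested. At these depths, simulated 2-fold changes were often missed.

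For pregnancy in conventional mice, fitting only the groups compared gave 497 higher and DESeq2 896 lower. In germ-free mice, limma-voom gave 1818 higher and 1209 lower, and DESeq2 876 lower. For germ-free status in non-pregnant mice, higher genes numbered 41 with limma-voom, 55 with DESeq2 and 24 without the pair of libraries. Lower genes numbered 18 with no low-count filter, 18 with only the groups compared, 51 with limma-voom, 62 with DESeq2, 28 without the farthest libraries and 22 without the pair. In pregnant mice, higher genes numbered 20 with no filter, 2 with only the groups compared, 64 with DESeq2 and 5 without the pair, and lower genes 15, 3 and 44 in the first of these 3 settings, 19 with limma-voom and 22 without the farthest libraries. The interaction gave 1 higher and 1 lower gene with no filter, a stricter filter or limma-voom, 2 and 5 with DESeq2, and 1 higher without the pair. Germ-free calls shared by non-pregnant and pregnant mice numbered 16 with DESeq2 and 13 without the farthest libraries.

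With each library left out in turn, higher and lower genes ranged from 659 to 1134 and 377 to 668 for pregnancy in conventional mice, and from 810 to 1322 and 384 to 768 in germ-free mice. Germ-free status gave 5 to 16 and 5 to 14 in non-pregnant, and 2 to 20 and 2 to 11 in pregnant mice. The interaction gave 0 to 1 in each direction. Shared calls ranged from 687 to 1052 for pregnancy and from 2 to 5 for germ-free status.

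Without the farthest libraries, without the pair, and without conventional pregnant replicate 2 alone, the pregnancy change in conventional mice turned for Cxcl10 (-0.42, -0.35 and -0.35), Prtn3 (-1.44, -1.60 and -1.60, and -0.60 with limma-voom) and the interferon list (adjusted p of 0.46, 0.403 and 0.394). The cell cycle list turned in the same settings for germ-free status in pregnant mice (0.003, 0.344 and 0.367). With other libraries left out singly, the far ends were 4.99 for Cxcl10, 4.85 for Prtn3, 0.00165 for the interferon list and 1.36e-07 for the cell cycle list. Without the farthest libraries, the T and NK cell list turned for pregnancy in conventional mice (0.0482). For germ-free status in pregnant mice, the MHC class II (0.732), periportal (0.567), T and NK cell (0.732) and neutrophil (0.913) lists turned, and for the interaction the T and NK cell (0.442) and neutrophil (0.988) lists.

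The replicate numbers did not pair the samples: of 21 pairs of groups and numbers, 5 had a correlation of deviations over 0.1 (range -0.26 to 0.31), and 5 samples correlated best with their own number. With the replicate number as a block, lower genes for germ-free status in non-pregnant mice numbered 19 and the interaction had 1 higher gene, and the other counts stayed within 1.5 times.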

Other observations

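The tests below were chosen after the results they bear on were seen, except the random splits for the cholesterol list. In germ-free mice, lipid genes moved in both directions with pregnancy. Of 24 cholesterol synthesis genes 2 rose, Tm7sf2, a sterol reductase, by 0.66 ± 0.21 among them, and none fell (2 adjusted over the list alone; list adjusted p = 0.202). Tm7sf2 lost its call in 7 of 11 fits that each left out 1 library (highest adjusted p = 0.146). Of 21 fatty acid and triglyceride synthesis genes, 1 rose, Fads1 by 1.16 ± 0.21, and 7 fell (4 and 8 adjusted over the list alone; list adjusted p = 0.0573). Of 30 PPAR-alpha target genes, 4 rose, Cyp4a31 by 2.05 ± 0.28 and Crat, a carnitine acetyltransferase, by 1.15 ± 0.18 among them, and 4 fell (6 and 5 adjusted over the list alone), and the list as a whole did not pass its test. Irs2, an insulin receptor substrate, rose by 2.15 ± 0.48 and Ppargc1a, a coactivator of gluconeogenesis genes, fell by 1.14 ± 0.25.

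Other groups in germ-free pregnancy included the sex-biased and zonal genes. Of 21 female-biased genes, 6 rose and 3 fell (7 and 5 adjusted over the list alone; list adjusted p = 0.0328, and adjusted p = 0.903 with an estimated correlation), and of 15 male-biased genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; list adjusted p = 0.591). Mup21 rose by 2.88 ± 0.45 and Mup20, a male-biased pheromone protein, fell by 2.94 ± 0.54, with estimated counts that were not whole numbers in 22 and 21 libraries. Of 18 pericentral genes, 1 rose and 3 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.0573), and Axin2, a Wnt target, fell by 0.96 ± 0.22. Of 17 periportal genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone; list adjusted p = 0.611, with a median of -0.27, a mean of 0.05 and a test on the lower side). Aldh1b1, a periportal aldehyde dehydrogenase, rose by 1.94 ± 0.30 and Hsd17b13, a lipid droplet enzyme, fell by 1.33 ± 0.21. Cyp7b1, of the alternative bile acid pathway, rose by 1.04 ± 0.24.

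Random splits were drawn 100 times per comparison, the real one included. For the number of genes called, 1 of 100 splits, the real one, reached the real total in each of the 4 comparisons. Totals were 1436 against at most 587 for pregnancy in conventional mice and 1713 against 966 in germ-free mice. They were 25 against 1 for germ-free status in non-pregnant mice and 21 against 2 in pregnant mice. Since the real split is counted, 1 of 100 is the lowest count possible. Chance is therefore argued against but not excluded. For the interaction the real total was 0 genes, which all 100 splits reach by construction, so this count decides nothing (highest other 15). For the number of lists called at the preset correlation, chance cannot be excluded in any comparison. As many lists were called in 38 splits for pregnancy in conventional mice (16 real, 22 highest other), 100 in germ-free mice (3 and 20), 59 for germ-free status in non-pregnant mice (9 and 19), 9 in pregnant mice (21 and 24) and 5 for the interaction (21 and 23). List by list, 1 of 100 splits gave a p as small for cholesterol synthesis and for handling and stress genes with germ-free status in non-pregnant mice, for P450 genes with germ-free status in pregnant mice and in the interaction, and for growth hormone and prolactin signalling in both pregnancy comparisons, of 35 lists in each.

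For the lower cholesterol synthesis list in germ-free non-pregnant mice, 1 of 100 splits of the 12 libraries, the real one, gave a p as small. This held for this list and for any list alike. The camera p at the preset correlation was 1.1e-39, against 1.78e-36 for the nearest other split. Another split thus also gave a very small p, and chance is not excluded. Neither the permutation test over 35 lists (adjusted p = 0.0505) nor camera with an estimated correlation (adjusted p = 0.0725) passed. A single library as the whole cause is argued against by the list mean, with a highest exact permutation p of 0.00649 when each was left out, although without germ-free non-pregnant replicate 2 the difference was -0.75 in place of -1.06. Age cannot be told apart from microbiota status, because 0 conventional libraries had an age label at or above the lowest germ-free one, so gut bacteria, age or housing may be the cause.

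Mup15 and Mup17 were far lower in germ-free non-pregnant mice. In these mice, reads moved between paralogs at an unchanged family total are argued against. The sum of 20 Mup genes differed by -2.27 in log2 CPM (exact permutation p = 0.00216). Moved reads together with a lower total cannot be excluded by this sum. In pregnant mice the sum differed by 0.05 (exact permutation p = 0.992), so there it does not argue against moved reads. That small difference rested in part on conventional pregnant replicate 2. Its sum was 671 CPM against 10300 to 18600 CPM in the rest of its group, and 3540 to 14300 CPM in germ-free pregnant mice. An unchanged total in pregnant mice is therefore not shown either. The share of the sum from Mup15 and Mup17 was at most 0.789% in the 11 germ-free libraries and at least 1.41% in the 11 conventional ones. A difference between the colonies at these genes may account for the share and cannot be told apart from microbiota status.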
